A study of Mus musculus with 12 samples.

How the data were processed

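The series measured RNA from mouse embryonic stem cells (strain label SV129) kept on gelatin in medium with leukemia inhibitory factor (LIF). Wild type cells (WT) and cells labelled as triple knockout of the retinoic acid receptor genes Rara, Rarb and Rarg (TKO) received ethanol vehicle or all-trans retinoic acid (ATRA) at 1 uM for 24 h. Each of the 4 groups had 3 libraries. Per the labels' protocols, RNA came from an RNeasy kit, libraries from an Illumina TruSeq RNA kit, and reads were single-end, 51 bp, from a HiSeq4000.

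The values used are FPKM (fragments scaled to transcript length and library size) per gene, as deposited by the authors. No header names the unit: it was taken from the values and from the submitters' processing notes, which name STAR, Cufflinks and GRCm38 without versions or roles. FPKM divides out library size and transcript length, so the total depth per library is unknown and no counting interval or count test was possible. Relative depth was read from genes under 0.05 FPKM, whose ratios between libraries lie at whole-number steps. Against the D library of WT vehicle, 104 to 225 of 416 to 663 such genes lay at 1 step in 10 libraries, and the depths of these 11 libraries ranged from 0.926 to 1.274. The D library of WT with ATRA showed no sharp step (32 of 443 genes), and its relative depth is not reported. The strand setting is not given in the sources used here, so genes that overlap another gene on the other strand are uncertain, as are genes with near-identical copies. The gene positions in the table are not GRCm38 positions: of 21994 symbols matched to the GENCODE vM21 annotation of GRCm38, 1013 started within 1000 bp of it. GRCm38 coordinates printed below therefore come from that annotation by symbol, and the table's own positions were used only for chromosome names and gene order.

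The table held 23686 rows. 18 rows that repeated another row exactly were removed, leaving 23668, of which 641 carried a symbol used more than once. 12362 genes with at least 1 FPKM in at least 3 libraries were tested. Columns name genotype, treatment and a letter (D, F or G), while sample titles number the replicates, so columns were assigned to groups and not to numbered samples. The labels do not say whether the 3 libraries of a group came from separate cultures, and p-values measure only the spread between these libraries.

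Tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with 1 mean per group over all 12 libraries (8 residual degrees of freedom), moderated with a mean-variance trend and robust settings, and Benjamini-Hochberg adjustment within each comparison at 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. The comparisons were ATRA against vehicle in WT, the same in TKO, the difference of these effects, and TKO against WT in each treatment. 23 gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation; lists with under 5 measured members were not tested. The lists share members: 16 of the retinoic acid target genes are also in another list. Comparisons, lists, the rule for naming genes and the first alternatives were fixed before the data were examined; further alternatives were added after. The rule names Rara, Rarb and Rarg; the 8 largest rises and 8 largest falls among called genes whose libraries do not overlap between groups and whose higher group has a mean of at least 1 FPKM, without predicted or small RNA genes and repeated symbols; and up to 4 members per list with the smallest adjusted p. Results for some genes that the rule names are not reported here.

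Whether letters pair libraries was checked on deviations from group means. Libraries of the same genotype and letter correlated at 0.376 to 0.864, while same-letter libraries of different genotypes correlated at −0.515 to 0.287. Libraries of different letters correlated at −0.730 to 0.315 within a genotype and at −0.405 to 0.600 between genotypes. The letters therefore pair libraries within a genotype and not between genotypes, from the data and not from the labels. The pairing was weakest for D in WT (0.376). Some spread was also shared between genotypes under different letters, as between G in WT and F in TKO. Fits with the letter as a block within genotype were added after seeing the data, because the columns do not carry the replicate numbers of the titles.

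The test was run on simulated values with the means and residual spreads of the 12362 genes. Noise was drawn separately for each library, without the pairing by letter seen in the data. Changed genes were drawn from those with a mean log2(FPKM + 1) above 1. The shares therefore do not cover low genes or paired libraries. For ATRA in TKO the test recovered 46% of 50 genes raised 1.5-fold, 86% of 50 raised 2-fold, 98% of 50 raised 4-fold and 88% of 50 lowered 2-fold. For ATRA in WT the shares were 50%, 80%, 92% and 66%, and for TKO against WT in vehicle 34%, 64%, 98% and 78%. Of all calls, 7.69%, 5.36% and 4.86% were false in the WT, TKO and genotype simulations. These simulations used the same gene means and the same spread per gene, pooled over all 12 libraries. Their shares therefore differ only by the random draw and do not rank the comparisons. The TKO shares do not use the spread of TKO libraries alone. Alternatives covered pseudocounts of 0.1 and 0.01, filters on low values, median-of-ratios scaling, quantile normalization, library weights, the variance model, the libraries in the fit and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.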

Results

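RNA was measured in 12 libraries of mouse embryonic stem cells, 3 for each combination of genotype (WT or TKO) and treatment (vehicle or ATRA). ATRA is the acid form of vitamin A and the ligand of the nuclear receptors encoded by Rara, Rarb and Rarg. The design asks how gene expression in WT cells and in cells labelled as lacking all 3 receptor genes differs with and without ATRA. Values are FPKM, given as mean ± SD with n = 3 per group. Between 11397 and 12193 genes reached 1 FPKM in a library, and the 10 most abundant genes took 6.87% to 8.77% of a library's total. Replicates of a group correlated at 0.976 to 0.993 on the log scale, across genes that are not independent replicates.

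The targeted genes were still read in TKO cells. Rara (GRCm38 chromosome 11, 98927818 to 98974942) was at 11.1 ± 2.64 FPKM in WT vehicle and 18.8 ± 1.35 in WT with ATRA, against 8.54 ± 0.852 and 9.303 ± 0.799 in TKO. Rarg (chromosome 15, 102234938 to 102257517), the most abundant of the receptors, was at 47.99 ± 10.7 and 86.5 ± 12.9 in WT against 14.9 ± 2.87 and 15 ± 2.22 in TKO, a log2 difference of −1.61 ± 0.19 (SE; adjusted p = 2.5e-04) in vehicle. Rara and Rarb did not pass there (−0.32 and −0.26, adjusted p = 0.121 and 0.161). With ATRA in both genotypes Rara, Rarb and Rarg were all lower in TKO in limma. The log2 differences were −0.95, −2.83 and −2.45 (adjusted p = 3.7e-04, 1.2e-07 and 3.8e-06), which include the rise with ATRA in WT. Rarb (chromosome 14, 16430839 to 16819156) was at 0.361 ± 0.137 FPKM in WT vehicle, 6.57 ± 1.25 in WT with ATRA, 0.132 ± 0.00861 in TKO vehicle and 0.0516 ± 0.0318 in TKO with ATRA. In WT all 3 rose with ATRA, by 0.73, 2.47 and 0.85 (adjusted p = 0.00506, 5.0e-07 and 0.0109). A gene-level value does not show whether a transcript is intact, so the remaining Rara and Rarg signal does not measure receptor protein.

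**Figure D1:**
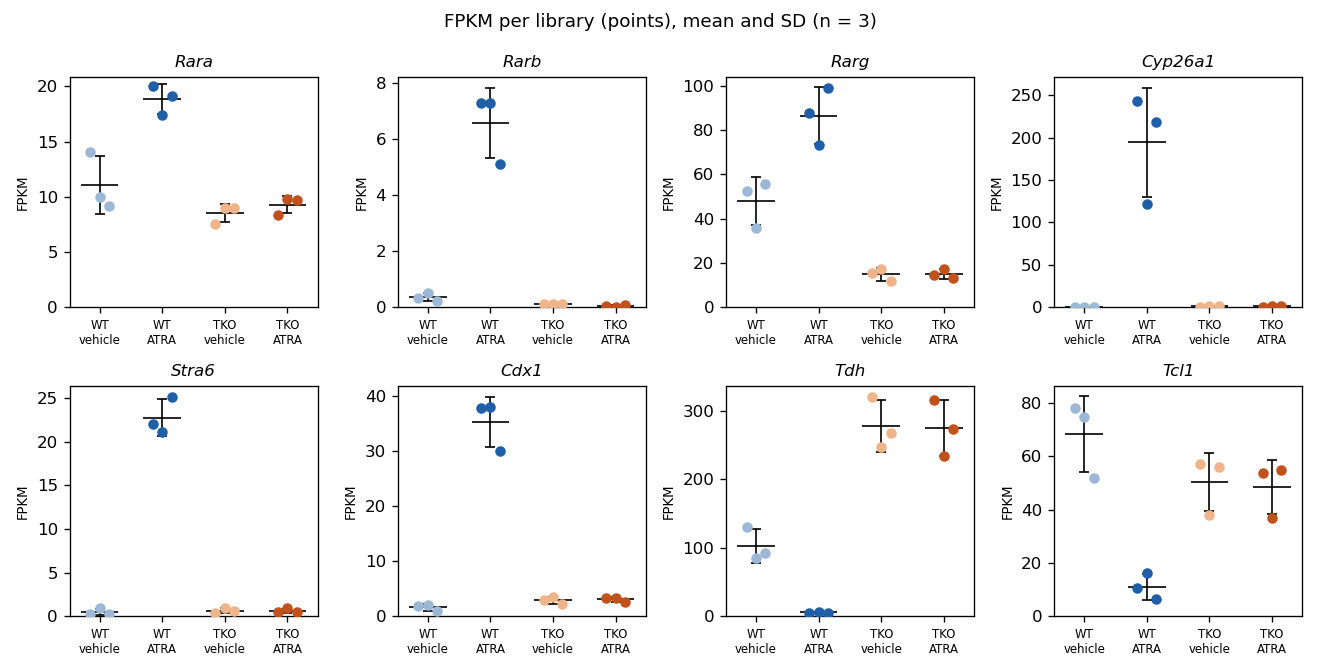
FPKM of the receptor genes, of the ATRA-induced genes Cyp26a1, Stra6 and Cdx1, and of the pluripotency-associated genes Tdh and Tcl1 in each library. Points are libraries, horizontal lines are group means and bars are SD (n = 3); Cyp26a1 averaged 194 FPKM in WT with ATRA and 1.49 in TKO with ATRA.

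In WT cells ATRA raised genes of retinoic acid handling and the Hox clusters and lowered genes of the pluripotent state. Cyp26a1, which encodes the enzyme that degrades retinoic acid, rose from 0.493 ± 0.191 to 194 ± 63.96 FPKM, by 6.98 ± 0.24 (log2, SE; adjusted p = 2.3e-08). The retinol transporter gene Stra6 rose from 0.5003 ± 0.363 to 22.7 ± 2.11 FPKM, and Dhrs3, a retinaldehyde reductase gene, from 0.568 ± 0.121 to 17.7 ± 4.67. The homeobox gene Cdx1 rose from 1.65 ± 0.655 to 35.3 ± 4.53 and the zinc finger gene Zfp703 from 0.112 ± 0.0752 to 10.8 ± 2.51. Among falls, Tdh, the threonine dehydrogenase gene active in mouse embryonic stem cells, went from 103 ± 24.5 to 5.75 ± 0.898 FPKM, by −3.93 ± 0.17 (adjusted p = 2.1e-07).

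Of the 20 measured retinoic acid target genes, 18 rose and 0 fell (camera adjusted p = 4.3e-20; adjusted p = 0.00656 with an estimated correlation), and the same 18 was the count adjusted over the list alone. Of 20 measured Hox genes, which set position along the body axis, 19 rose (adjusted p = 4.2e-28; 0.0225 as adjusted p with an estimated correlation). Hoxb2 went from 0.008001 ± 0.0139 to 18.7 ± 3.96 FPKM, Hoxa5 from 0.259 ± 0.1499 to 21.9 ± 3.18, Hoxa3 from 0.349 ± 0.178 to 12.8 ± 2.04 and Hoxa4 from 0.603 ± 0.0528 to 14.03 ± 1.93. Of 18 genes of retinoid metabolism 9 rose and 2 fell, or 10 and 2 adjusted over the list alone (adjusted p = 0.00136; adjusted p = 0.02701 with an estimated correlation and 0.0603 with the letter block).

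Of 31 pluripotency genes 21 fell and 2 rose, or 24 and 2 adjusted over the list alone (camera adjusted p = 5.2e-15; adjusted p = 0.02701 with an estimated correlation). Zfp42, a marker of naive stem cells, fell from 544 ± 46.3 to 153 ± 38.7 FPKM, the nuclear receptor gene Nr0b1 from 118 ± 17.1 to 24.9 ± 9.67, and the growth factor gene Fgf4 from 70 ± 12.4 to 23.97 ± 5.32. Other large falls were Tcl1, a coactivator of AKT kinase, from 68.1 ± 14.2 to 11.1 ± 4.79, Ly6g6e from 29.2 ± 14.7 to 2.83 ± 2.06 and Serpinb6c from 19.97 ± 6.46 to 2.23 ± 1.01. Enox1 fell from 10.7 ± 0.773 to 1.18 ± 0.446, Nkx6-3 from 7.89 ± 2.43 to 0.7902 ± 0.386 and Slc17a9 from 12.5 ± 2.66 to 1.99 ± 0.546. Of 16 genes of LIF and STAT3 signalling 6 fell and 2 rose, or 6 and 3 adjusted over the list alone (adjusted p = 0.0403; adjusted p = 0.233 with an estimated correlation and 0.187 with the letter block). Socs2, a feedback inhibitor of cytokine signalling, fell from 21.8 ± 3.75 to 9.02 ± 1.31 and Klf4 from 119 ± 16.9 to 60.8 ± 19.6.

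Of 20 extraembryonic endoderm genes 7 rose, or 12 adjusted over the list alone (adjusted p = 0.00213; adjusted p = 0.393 with an estimated correlation). The transcription factor gene Gata6 rose from 1.08 ± 0.413 to 11.9 ± 3.68 FPKM, and Sox7 from 2.31 ± 0.3797 to 7.68 ± 1.44. Of 15 germline and meiosis genes 6 rose, as many as adjusted over the list alone (adjusted p = 0.004499; adjusted p = 0.422 with an estimated correlation). Stra8, required for entry into meiosis, rose from 119 ± 40.8 to 759.9 ± 74.8 FPKM, and Rec8, a meiotic cohesin gene, from 7.52 ± 1.53 to 20.7 ± 4.03. Of 16 TGF-beta and BMP target genes 9 rose and 1 fell, or 9 and 2 adjusted over the list alone (adjusted p = 0.004499; adjusted p = 0.197 with an estimated correlation). Skil rose from 13.6 ± 0.918 to 51.03 ± 10.7. Of 32 cell cycle genes 3 fell and 1 rose, or 1 and 0 adjusted over the list alone (adjusted p = 0.00821; adjusted p = 0.197 with an estimated correlation). The primed epiblast list (7 rose and 2 fell of 14) had an adjusted p of 0.0529, the neural list (3 rose and 5 fell of 16) 0.0674 and the mesoderm list (3 rose of 6) 0.0594.

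In all, 2063 of 12362 genes passed the threshold, 1428 higher and 635 lower, of which 261 and 130 changed at least 2-fold. The share of rises for the ATRA effect in wild type cells, 69.2%, depended on scaling: it was 50.7% with median-of-ratios scaling and 55.5% with quantile normalization. The libraries of the 2 groups did not overlap for 34.4% of genes, where chance gives 10% for libraries that are not paired. With the letter as a block within genotype 6887 genes were called, 4171 higher and 2716 lower, and without the D library of WT vehicle or of WT with ATRA the count was 1312 or 1189; the latter library alone lacked sharp read steps among low genes.

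In TKO cells 0 genes passed the threshold for ATRA against vehicle in limma, and 12 had an unadjusted p under 0.05. Cyp26a1 was at 1.36 ± 0.325 FPKM in vehicle and 1.49 ± 0.414 with ATRA, Stra6 at 0.646 ± 0.305 and 0.646 ± 0.248, and Cdx1 at 2.93 ± 0.612 and 3.08 ± 0.444. Stra8 was at 13.5 ± 3.199 and 13.2 ± 2.38. Tdh was at 278 ± 37.9 and 275 ± 40.9, Zfp42 at 550.4 ± 76.4 and 526 ± 80.4, and Nr0b1 at 113 ± 10.9 and 115 ± 13.8.

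For Cyp26a1 the 95% interval of the log2 change in TKO was −0.45 to 0.588, for Stra6 −0.405 to 0.418, for Dhrs3 −0.396 to 0.388, and for Rarb −0.387 to 0.175. With TKO libraries only and the letter as a block they were −0.0746 to 0.213, −0.151 to 0.164, −0.201 to 0.193 and −0.26 to 0.0472. Cyp26a1 was higher with ATRA in all 3 TKO pairs, Rarb in 0. 0 members of the 20 retinoic acid target genes, 20 Hox genes, 31 pluripotency genes and the other lists passed the threshold, adjusted over the list alone as well. The lowest camera adjusted p of a list was 0.267, for Hox and for WNT targets. With the letter block within genotype it was 0.0512, for WNT targets (toward higher values) and for the stress response (toward lower values). With a pseudocount of 0.1 the Hox list passed (camera adjusted p = 0.0157, median log2 change 0.147), on genes whose TKO values lie near 0, such as Hoxa5 at 0.0487 ± 0.0283 and 0.104 ± 0.0613 FPKM. The 1428 genes that rose in WT had a median log2 change of 0.634 there and 0.0045 in TKO, and the 635 that fell had −0.618 and −0.0037. Over all 2063 the slope of the TKO change on the WT change was 0.0077 ± 0.0073 (SD over 3 letters).

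Of 12362 unchanged genes 618.1 would be expected to have an unadjusted p under 0.05, against the 12 observed. For 1.34% of genes the libraries did not overlap between treatments, where chance gives 10%. Both expected values hold for libraries that are not paired. The letters pair TKO libraries, so fewer such genes are expected here. The spread between letters enters the error of the fit without a block, which limits its count of 0. With the letter as a block within genotype the count past the threshold was 0. With only TKO libraries and the letter as a block, 829 genes had an unadjusted p under 0.05 and 3 passed the threshold: Akr1b3, Snora64 and Snora70, named after their values were seen. Akr1b3, an aldose reductase gene (chromosome 6, 34302434 to 34317478), went from 13.3 ± 1.15 to 23.8 ± 1.49 FPKM in TKO (log2 change 0.80, adjusted p = 0.0013). In all other fits the adjusted p was 0.431 to 1, while the change was 0.76 to 0.86 in every fit; its SE was 0.0469 with TKO libraries only and the block, 0.0957 with TKO libraries only, 0.179 in the fit of all 12 libraries and 0.231 in that fit with the block within genotype. For the difference of effects Akr1b3 passed in the fit of all 12 libraries without a block (1.28, adjusted p = 0.0138), with a fall in WT from 25.4 ± 7.23 to 17.7 ± 3.12 FPKM (log2 change −0.48, adjusted p = 0.096). The annotation has an antisense gene across Akr1b3. For 12171 of 12362 genes in the fit of all 12 libraries the 95% interval of the TKO effect lay within 1 log2 unit of 0. On the log2(FPKM + 1) scale, genes near 0 FPKM in TKO, such as Rarb and Hoxb2, can lie within it even with a large fold change. The median distance from estimate to interval end was 0.302 in the fit of all 12 libraries and 0.113 with TKO libraries only and the block. Vehicle and ATRA libraries of the same letter were closer to each other in TKO (median absolute deviation of the log2 ratio 0.0958, 0.0875 and 0.129) than TKO libraries of 1 group with different letters (0.18 to 0.439), and no gene measured here shows separately that ATRA reached these cells.

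**Figure D2:**
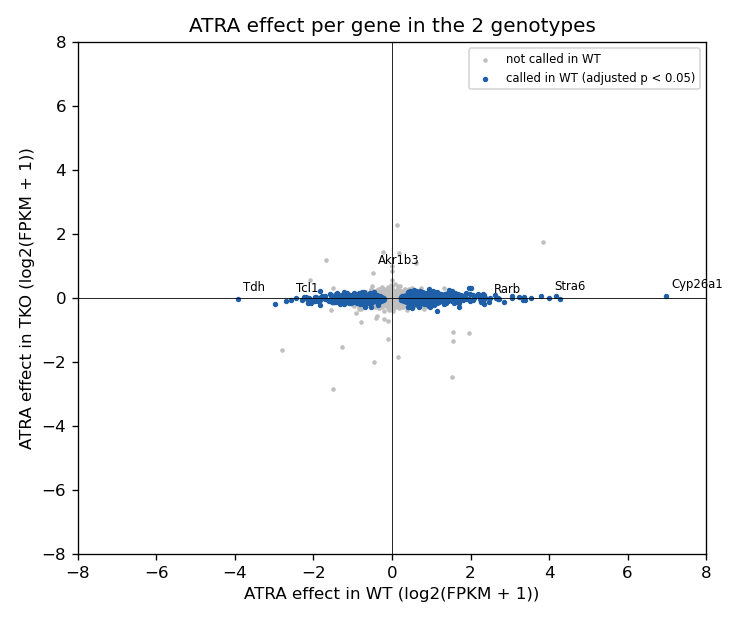
Log2 change with ATRA per gene in WT (horizontal axis) and in TKO (vertical axis), both on the log2(FPKM + 1) scale. Blue points are the 2063 genes called in WT; they spread from −3.93 (Tdh) to 6.98 (Cyp26a1) along the WT axis, and none passed the threshold in TKO.

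The difference between the effects was tested directly, and the genes whose effect differed included the largest rise and the largest fall in WT, Cyp26a1 and Tdh. The log2 effect in TKO minus that in WT was −6.91 ± 0.33 for Cyp26a1 (SE; adjusted p = 1.2e-06), −4.30 ± 0.19 for Hoxb2 and −3.55 ± 0.25 for Dhrs3. For Tdh it was higher by 3.91 ± 0.24 (adjusted p = 9.6e-06) and for Nr0b1 by 2.28 ± 0.30. Of the listed genes, 15 of 20 retinoic acid targets and 19 of 20 Hox genes had a lower effect in TKO, or 17 and 19 adjusted over the list alone (camera adjusted p = 9.1e-25 and 2.1e-35; adjusted p = 0.00315 and 0.01104 with an estimated correlation). 11 of 31 pluripotency genes had a higher effect, or 19 and 2 lower adjusted over the list alone (adjusted p = 3.8e-15; adjusted p = 0.0263 with an estimated correlation). Rara and Rarg did not pass the limma test of the difference in the fit without a block (−0.62 and −0.84, adjusted p = 0.114 and 0.108). The error of that fit includes the spread between letters, so this does not show that their effects were equal.

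671 genes differed, 489 with a lower and 182 with a higher effect in TKO, and 670 of them were also called for ATRA in WT. For the difference of the ATRA effects between genotypes the share with a higher effect, 27.1%, was 40.8% with median-of-ratios scaling and 40.0% with quantile normalization. With the letter as a block within genotype 4820 genes differed, 1760 with a higher and 3060 with a lower effect. The count was 444, 406, 413 and 447 without the D library of WT vehicle, of WT with ATRA or of TKO vehicle, or the G library of TKO with ATRA.

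Without ATRA, TKO cells already differed from WT cells in single genes such as Stra8, Otx2 and Tdh. Stra8 (chromosome 6, 34920163 to 34939344) was lower, at 13.5 ± 3.199 FPKM against 119 ± 40.8 in WT, a log2 difference of −3.02 ± 0.23 (SE; adjusted p = 1.9e-05). Otx2, a homeobox gene of the primed epiblast, was higher at 20.1 ± 1.45 against 2.32 ± 0.8903, by 2.70 ± 0.19 (adjusted p = 1.2e-05). Anxa1, which encodes a phospholipid-binding protein, was at 13.1 ± 5.57 against 0.337 ± 0.0667 and Hand1, a trophoblast and mesoderm transcription factor gene, at 12.7 ± 7.77 against 0.764 ± 0.362. Tdh was higher at 278 ± 37.9 against 103 ± 24.5 (adjusted p = 2.7e-04).

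Other genes higher in TKO were Ntn1, at 18.5 ± 8.27 against 2.201 ± 2.24 FPKM, and Efhc2, at 8.14 ± 1.69 against 0.365 ± 0.122. The imprinted growth factor gene Igf2 was at 9.903 ± 5.696 against 0.677 ± 0.0902, Cyr61 was at 12.4 ± 2.28 against 1.39 ± 0.401, and the Y-linked helicase gene Ddx3y at 24.4 ± 5.94 against 1.66 ± 0.706. Genes lower in TKO were Igsf21, at 2.695 ± 0.391 against 19.3 ± 0.482, the kinase gene Camk1, at 3.62 ± 0.503 against 24.9 ± 8.86, and Pttg1 (securin), at 21.96 ± 4.09 against 122 ± 32.5. Pacsin1 was at 1.75 ± 0.633 against 12.2 ± 2.52, and Fbxo2 at 8.42 ± 1.08 against 40.6 ± 4.02. Prrx2 was at 2.39 ± 0.6096 against 13.4 ± 0.642, and the peptide transporter gene Slc15a1 at 1.45 ± 0.233 against 9.27 ± 1.35.

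Of 20 extraembryonic endoderm genes 12 were higher and 1 lower in TKO, or 14 and 1 adjusted over the list alone (camera adjusted p = 5.6e-05; adjusted p = 0.763 with an estimated correlation). They included the laminin gene Lamb1, at 29.8 ± 5.68 against 12.4 ± 0.677 FPKM, Sox17, at 1.58 ± 0.285 against 0.494 ± 0.207, and Dab2, at 7.28 ± 1.61 against 2.34 ± 0.775. Of 14 primed epiblast genes 5 were higher, as many as adjusted over the list alone (adjusted p = 0.00673; adjusted p = 0.137 with an estimated correlation), among them Cdh2, at 1.801 ± 0.181 against 0.292 ± 0.0929. Of 21 p53 and apoptosis genes 8 were higher and 1 lower, or 9 and 1 adjusted over the list alone (adjusted p = 0.0342; adjusted p = 0.763 with an estimated correlation, 0.0799 with a letter block shared by the genotypes, which the pairing check does not support and 0.0725 with median-of-ratios scaling). Mdm2 was at 65.04 ± 4.41 against 39.7 ± 0.735 and Trp53inp1 at 63.9 ± 1.61 against 31.7 ± 7.28. The retinoic acid target list did not move as a set (4 higher and 3 lower of 20, median log2 difference 0.02, mean −0.08, adjusted p = 0.969), nor did the pluripotency list (5 higher and 5 lower of 31, adjusted p = 0.919).

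3046 genes passed the threshold, 1462 higher and 1584 lower in TKO, of which 231 and 177 differed at least 2-fold. Without the D library of WT vehicle or of TKO vehicle the count was 1934 or 1942. 558 of them, 18.3%, lay on chromosomes 6, 11 and Y, which hold 13.4% of tested genes. The median log2 difference of chromosome 6 genes from other autosomes was −0.207 in vehicle (95% bootstrap interval −0.237 to −0.162, 589 genes), and that of chromosome 11 genes was 0.237 (0.211 to 0.267, 1062 genes). These intervals resampled genes and leave out the spread between libraries. Against the WT vehicle mean, the D, F and G libraries of TKO vehicle were at −0.240, −0.184 and −0.146 on chromosome 6. On chromosome 11 they were at 0.288, 0.253 and 0.199. With these differences and that of Y-linked genes such as Ddx3y, a difference between TKO and WT cells cannot be ascribed to loss of the receptors alone.

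**Figure D3:**
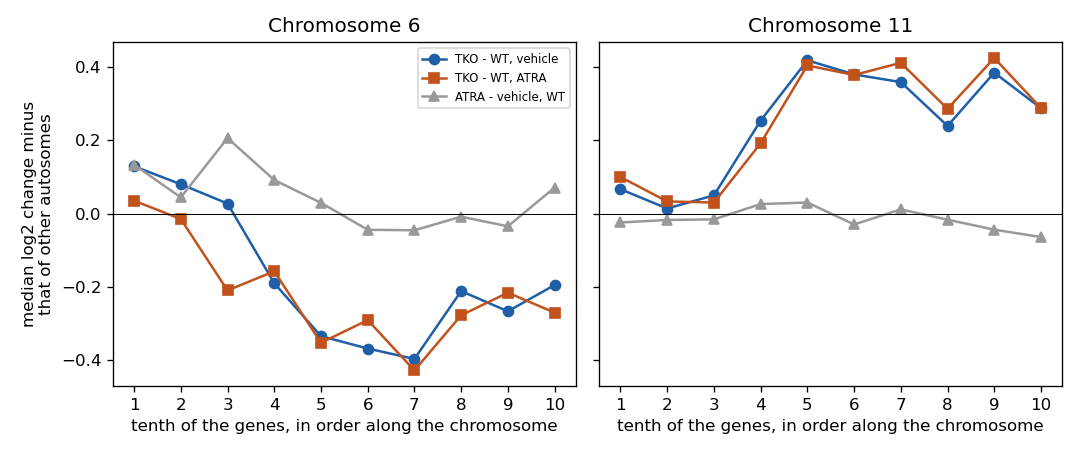
Median log2 difference of genes on chromosomes 6 and 11, relative to the median of the other autosomes, in 10 groups of neighbouring genes along each chromosome. Blue circles are TKO against WT in vehicle, which reach −0.396 on chromosome 6 and 0.417 on chromosome 11 from 0.129 and 0.0663 in the first groups; orange squares are TKO against WT in ATRA and grey triangles are the ATRA effect in WT.

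With ATRA in both genotypes, retinoic acid targets and Hox genes were lower and pluripotency genes higher in TKO. 18 of 20 retinoic acid targets were lower and 1 higher, the same counts as adjusted over the list alone (camera adjusted p = 8.0e-11; adjusted p = 0.0495 with an estimated correlation). 19 of 20 Hox genes were lower (adjusted p = 1.3e-15; adjusted p = 0.113 with an estimated correlation). 17 of 31 pluripotency genes were higher and 3 lower, or 18 and 4 adjusted over the list alone (adjusted p = 5.0e-06; adjusted p = 0.245 with an estimated correlation). Of 18 retinoid metabolism genes 8 were lower and 3 higher (adjusted p = 0.0379; adjusted p = 0.135 with an estimated correlation and 0.0711 with the shared letter block).

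5201 genes passed the threshold, 2023 higher and 3178 lower in TKO, of which 428 and 716 differed at least 2-fold. For triple knockout against wild type in ATRA the share of higher genes, 38.9%, was 51.8% with median-of-ratios scaling and 49.4% with quantile normalization. This comparison equals the vehicle difference plus the difference of effects, so it is not independent of them. Genes called for ATRA in WT and for TKO against WT in vehicle overlapped most where ATRA raised and TKO lowered them (331 genes, 183.0 expected of independent lists). The counts were 193 (168.9) for raised and higher, 110 (75.1) for lowered and higher and 96 (81.4) for lowered and lower. The shared WT vehicle libraries add only to genes raised and higher or lowered and lower: unchanged groups, with WT libraries paired by letter as observed, gave a simulated correlation of 0.317 against −0.0602 observed and a covariance of 0.00704 against −0.0115.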

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

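The tests of the likeness of knockout pairs and the fits with the letter as a block were chosen after the result was seen. Apart from the receptor genes and Akr1b3, the genes named for ATRA were picked by the size or p of their change in these same WT libraries. Akr1b3 was named after its values were seen. How many of them differed is therefore not separate evidence of a difference. The ATRA effect differed between the genotypes in limma for 671 genes and for 46 of 90 genes named for ATRA. The log2 effect in TKO minus that in WT was negative for 29 of these: Cyp26a1 −6.91, Hoxb2 −4.30, Hoxa5 −4.11, Stra6 −4.00, Cdx1 −3.74, Dhrs3 −3.55, Zfp703 −3.44, Hoxa3 −3.31, Hoxa4 −3.18, Stra8 −2.73, Rarb −2.57, Gata6 −2.51, Sox4 −2.36, Nrip1 −2.06, Skil −1.84, Rec8 −1.38, Sox7 −1.31, Ndn −1.29, Serpinh1 −1.29, Dusp9 −1.28, Sfrp2 −1.28, Nnat −1.24, Ctgf −1.13, Fgfr2 −1.12, Esx1 −1.01, Sall2 −0.88, Plat −0.79, Sox1 −0.70, Mdm2 −0.57. It was positive for the other 17: Tead4 0.86, Thy1 0.91, Sfrp1 1.00, Nr5a2 1.02, Otx2 1.13, Socs2 1.26, Akr1b3 1.28, Fgf4 1.5, Zfp42 1.78, Slc17a9 2.23, Nkx6-3 2.24, Nr0b1 2.28, Enox1 2.44, Tcl1 2.52, Serpinb6c 2.62, Ly6g6e 2.79, Tdh 3.91.

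For ATRA in WT 1 of the 10 splits of the 6 libraries called as many genes as the real 2063 (the highest other called 1, and 0 among splits that part every letter). For TKO against WT 1 of 10 did so in vehicle (3046, highest other 0) and 1 of 10 in ATRA (5201, highest other 1), and for ATRA in TKO all 10 did (0, highest other 1). With 10 splits no share under 0.05 is possible. With TKO libraries only and the letter block, which called 3 genes, exchanging the labels of pair D, F or G called 0, 0 and 1. Genes with an unadjusted p under 0.05 were 829 with the real labels and 271, 1066 and 312 with these exchanges, so the 829 are not more than an exchange of labels can give. For the difference of effects, 12 of 100 drawn splits of the treatment labels within genotypes called at least 671 genes, with 1581 the highest, so by that share chance is not excluded. 11 of the 12 kept the true WT labels, and with them the WT response, so they do not represent libraries without an effect. Of the 89 splits with other WT labels 1 reached 671, with 1324 genes. It kept both F libraries of each genotype on 1 side; why it called genes was not tested, and the fit with the letter block within genotype gave 4820.

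The vehicle and ATRA libraries of 1 letter were nearly alike in TKO, which bears on how the count of 0 is read. That 1 set of reads stands under both treatments, processed alike, is argued against by 0 identical nonzero values in every pair (of 12335 to 12341 genes). The pair differences of the 3 letters were uncorrelated across genes (−0.101 to 0.0473, against 0.767 to 0.829 in WT). A lack of response and 1 library sequenced again would both give such correlations, so they decide between neither. 1 library sequenced again stays open: 1 gene other than small RNA genes, Akr1b3, differed alike in all pairs (log2 ratios 0.914, 0.727 and 0.755), fewer than the several genes set to exclude it. Among 8643 genes with a mean of at least 5 FPKM in TKO, small RNA genes left out, Akr1b3 ranked 3, 2 and 3 by size of ratio. A bound of 1 such extreme gene, also written after the result was seen, would have been met. Pairs made from 1 split culture are a candidate explanation: over 5535 genes with an adjusted p above 0.5 in WT, the residual SD of pair differences was 1.499 times as large in WT as in TKO (95% bootstrap interval 1.46 to 1.54), a value at the bound set for it. The interval resampled genes and not the 3 pairs of each genotype, so it cannot place the ratio on either side of that bound. Whether ATRA was without effect for a reason other than genotype, such as treatment or labels, cannot be told apart from a lack of response, since 0 of 16 PPAR targets passed the threshold and both predict that; the genotype difference that the design names stays open.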

How the results depend on the processing

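Fits with the letter as a block, with the 6 libraries and the block, without both knockout F libraries, and without genes of chromosomes 6, 11 and Y, and quantile normalization for lists, were chosen after seeing the data. The replicate numbers of the titles could not be used as a block because the columns carry letters. For ATRA in WT (2063 genes) the count was 1086 with a mean FPKM of at least 5, 6607 with library weights, 6887 with the letter block within genotype, 5695 with 6 libraries and that block, 391 at 2-fold or more, and 1189 to 2179 with 1 library left out. For the difference of effects (671) these were 263, 3987, 4820 (within genotype), 305 at 2-fold or more, and 406 to 710. For TKO against WT in vehicle (3046) library weights gave 7828, 2-fold or more 408, and leaving out 1 library 1934 to 3172. In ATRA (5201) the counts were 3425 with a mean FPKM of at least 5, 7985 with weights, 1144 at 2-fold or more, and 4026 to 5443 with 1 library left out. For ATRA in TKO (0) they were 1 with only the 6 libraries and 3 with the 6 libraries and the block, and 0 in every other fit, each library left out included. Fewer genes tested or a fold minimum lower a count by construction; the cause of the other moves was not tested. A letter block shared by both genotypes, which the pairing check does not support, gave 2329, 0, 890, 3328 and 5356. Without both knockout F libraries the counts were 2533, 0, 578, 2757 and 4894, and without chromosomes 6, 11 and Y 2436 in vehicle and 4392 in ATRA. No named gene or list turned its direction where either fit called it; of all called genes, 9 of the 3046 changed sign with quantile normalization. Apart from single libraries left out, 4503 named-gene values stayed on their side of the threshold, 94 lost and 62 gained a call; with 1 library left out these were 4096, 193 and 19. Of list values 464 stayed, 25 lost and 11 gained a call. No scaling moved the median of all genes by over 0.1. The total depth is unknown, so the limit it sets on low genes cannot be given; the relative depths of 11 libraries spanned 1.38-fold.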

Other observations

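The tests with the letter as a block, the ratios of Y-linked genes, the share of a chromosome's genes on its side and the offsets of parts of a chromosome against each other were chosen after the result was seen. Genes of imprinted loci were among those that differed without ATRA: of 19 measured, 6 were higher and 1 lower in TKO vehicle (camera adjusted p = 0.1004). Plagl1, a growth-regulating zinc finger gene, was at 3.69 ± 0.693 FPKM against 0.0111 ± 0.00459 in WT, and Mest at 78.4 ± 3.63 against 33.4 ± 4.57. Among signalling targets, Id2, a target of BMP, was at 14.5 ± 1.06 against 3.77 ± 1.24, Axin2, a WNT target, at 3.32 ± 0.947 against 1.14 ± 0.356, and Ctgf at 15.04 ± 2.71 against 2.62 ± 0.546, while Dusp9 was lower at 27.7 ± 4.503 against 76.2 ± 11.98. Krt18, a simple epithelial keratin gene, was at 30.95 ± 16.5 against 5.78 ± 0.313.

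Of the other lists, ATRA in WT gave these camera results: trophoblast (2 rose and 2 fell of 13) an adjusted p of 0.823, fibroblast and feeder markers (3 and 1 of 7) 0.296, p53 and apoptosis (3 and 0 of 21) 0.586, PPAR targets (3 and 3 of 16) 0.586, nuclear receptors (8 and 3 of 26) 0.195, WNT targets (4 and 2 of 12) 0.374, stress response (0 and 0 of 20) 0.399 and imprinted genes (2 and 2 of 19) 0.702. The medians of the trophoblast and imprinted lists were above 0 (0.15 and 0.01) while camera ranked both lists toward lower values. The 2-cell-like list had 1 measured member, the list of Y genes and Xist 4 and the RNA quality list 2, and none of their members passed the threshold for ATRA in WT.

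Ddx3y (chromosome Y, 1260771 to 1286629) and Uty (chromosome Y, 1096861 to 1245759) were low in every WT library: the highest WT value of Ddx3y was 0.155 of the lowest TKO value, and Uty was at 0.318 ± 0.0123 FPKM in WT vehicle against 6.51 ± 2.08 in TKO. Eif2s3y differed less, with a WT mean 0.635 of the TKO mean.

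Genes of chromosome 6 were lower and genes of chromosome 11 higher in TKO in both treatments (−0.235 and 0.243 in ATRA). After regression on GC content, transcript length and expression the smallest of the 4 offsets was 0.209 in the chromosome's direction, which argues against such a bias as the cause. A change in a few genes of each chromosome is argued against because at least 67.3% of a chromosome's genes (95% bootstrap interval 64.6% to 70.2%) lay on its side of the median of the other autosomes. This interval and those below resampled genes and leave out the spread between libraries. The test first planned left out called genes, which filters on the change itself. Its offsets on chromosomes 6 and 11 were −0.113 and 0.105 in vehicle and −0.0764 and 0.0653 in ATRA. The smallest lay between the bounds set, so that test did not decide. A copy number difference of the whole chromosomes is argued against because the smallest offset of 4 parts, over the mean of both treatments, was −0.17 times the median of the other parts on chromosome 6 (interval −0.478 to 0.169) and 0.196 times on chromosome 11 (0.0916 to 0.431); in its direction the first part of chromosome 6 was at −0.0896 in vehicle and 0.0184 in ATRA (−0.0594 to 0.125), and that of chromosome 11 at 0.0637 (0.0142 to 0.125) and 0.0842 (0.0182 to 0.162), above the 0.05 first set for such a difference. Copy number of a part of either chromosome and any other difference between the genotypes were not tested and stay open.

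Akr1b3, Snora64 and Snora70 were called for ATRA in TKO with the 6 libraries and the letter block. Small nucleolar RNA genes had median absolute changes 14.5 times those of other genes in TKO (0.568 against 0.0392) and changed about as much in WT (0.495 against 0.184). In every TKO pair Snora70 rose with ATRA (means 6.81 and 37.5 FPKM) and Snora64 fell (119 and 73.2). The size of changes does not test this agreement in direction. Unstable FPKM of small RNA genes may account for Snora64 and Snora70, but was not tested against it. Akr1b3 is not such a gene, and reads shared with its family are argued against because the lowest change of a tested Akr1b gene was −0.0567. Its log2 change was 0.76 to 0.86 in every fit, its adjusted p 0.0013 in that fit (SE 0.0469) and 0.431 to 1 in others (SE 0.0957 with the 6 libraries, 0.179 with all 12, 0.231 with all 12 and the block within genotype), and its difference of effects passed (1.28, adjusted p = 0.0138). Reads from the antisense gene across it and an ATRA effect without these receptors were not tested.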
